A study of Mus musculus with 6 samples.

How the data were processed

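RNA abundance was measured in 6 aortic arches, 1 per array, from female mice whose strain label was C57BL/6. Per the labels, Mir21+/+ recipients had received whole-body X-rays in 2 fractions of 5 Gy within 4 h, followed by bone marrow from either Mir21+/+ or Mir21–/– donors. High-fat feeding began 3 weeks after irradiation and lasted 12 weeks. Arch RNA with an integrity number above 7.5 was labelled with Cy3 from 100 ng per sample. The groups held 3 arrays each, and the series design states that these were 3 mice per group.

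The deposited scanner files held 1 colour, read with Agilent Feature Extraction 10.7.3.1, per the file headers. Their processed signal is an intensity on a linear scale from which, per the file headers, the authors' scanner software had subtracted background, removed spatial trends and replaced low values by a surrogate. It was not normalized between arrays. The deposited series table held the same intensity values rounded to 3 significant digits, to within 0.5%, so that scale, centring and direction were settled, and the column medians ran from 32.1 to 54.3. Spot flags for brightness above background, saturation and outliers were the software's own.

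Each of the 62976 spots per array was either a control or one of 59305 spots carrying 55681 probes. The main values were log2 processed signals minus each array's 75th percentile over the spots that were not controls, with outlier spots left out and the spots of a probe averaged. A probe was tested where it lay well above background on all 3 arrays of at least 1 group, which left 38341 probes after 10 were set aside for outlier spots. Gene names came from the accession in the files for 27509 probes, the name for 3549 and an older synonym for 404, through a RefSeq gene table. A further 1350 kept the file's name, and 22869 had none. Coordinates are those the scanner files give on mm9. The position of probes relative to exons, introns and untranslated regions was not analysed here.

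Knockout minus wild-type differences were fitted with lmFit and eBayes from limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Gene lists were tested with camera at its preset correlation of 0.01, taking the brightest tested probe per gene. Of the 36 lists fixed before the data were examined, the 35 with at least 5 measured genes were tested. Counts of changed members are also given adjusted over the list alone, and medians carry a 95% bootstrap interval from 10000 resamples over genes. A probe not well above background on any array of a group has only a bound there. The fold is then given as "at least", from the bright group's mean against the dim group's mean of the higher of the lowest signal well above background on that array and the probe's own.

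The genes to name were also fixed beforehand. They comprised Mir21, Xaf1 and Pdcd4, the 12 genes per direction with the largest difference among those past the adjusted test, filled up with genes of unadjusted p below 0.01, and the 4 members with the smallest p of each list past its test. Names of uncharacterised transcripts kept their rank and were left unprinted where at least 8 others remained. When 200 simulated probes per run were shifted among the 38341 tested, over 5 runs, the fit recovered 11.2% of shifts of 1 on the log2 scale, 82.8% of shifts of 2 and 95.2% of shifts of 3. There were 45 false calls over the 5 runs. Variable probes were simulated as more regular than they are. The 200 shifts per run, up to 5 in size, also loosened the adjusted cut relative to the real data, where 1 probe passed. For both reasons these shares are upper estimates. In 175 tests of unshifted lists camera called 0, but members were simulated as independent of each other.

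The arrays gave 66.4% to 74.4% of spots well above background, with a 75th percentile of signal between 239 and 407 and 0 saturated spots. The lowest values of both belonged to knockout replicate 3. Precision is limited by the number of arrays. All arrays shared 1 slide and 1 scan, with wild-type arrays in slide row 1 and knockout arrays in row 2, so slide row and group cannot be told apart and no slide or scan block could be fitted. Alternatives covered background correction, normalization, the filter on dim probes, the authors' series table, a replicate block, leaving out each array, the variance model, array weights, the test and the threshold, and the list test. The adipocyte covariate, the fit without knockout replicates 2 and 3 and the list test for change in either direction were chosen after seeing the data. That covariate was each array's mean over the white and brown adipocyte markers, from these same arrays. It therefore takes out the difference of those lists by construction. Genes with miR-21 seed matches were not tested, since 3′ UTR sequences were not used here.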

Results

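Aortic arch transcript levels were compared between irradiated mice carrying wild-type or Mir21-deficient bone marrow after high-fat feeding. The question was which arch transcripts depend on miR-21 in marrow-derived cells, with the daily clock and apoptosis named in the series title. Each group held 3 mice, and 0 probes on the array carried the name of Mir21 or Mir21a, so the knockout itself could not be checked on these arrays. Values are log2 signals relative to the array's 75th percentile, and differences are knockout minus wild-type marrow.

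Genes of the circadian clock differed between the arches, and theirs was the list with the most members past the test when adjusted over the list alone. Bmal1 (listed as Arntl), the core activator of the clock, was 11.4-fold higher with knockout marrow, from -1.85 ± 1.17 to 1.66 ± 0.49 (SD, n = 3 per group). Its partner Npas2 was 5.91-fold higher, from -4.08 ± 0.44 to -1.51 ± 0.38, and Nfil3, a repressor of D-box genes, 6.54-fold higher. Npas2 was dim with wild-type marrow, though well above background on all 3 arrays, so its fold depends on the background correction. Ciart, a repressor of Bmal1-driven transcription, lay at -0.76 ± 0.22 with wild-type marrow and was not well above background on any knockout array, which made it at least 16.9-fold lower on the reported scale, while normexp, which adds an offset of 50 to every signal, gave a log2 difference of -1.95. Dbp, an output activator of the clock, was 18.2-fold lower, from 6.14 ± 0.59 to 1.95 ± 1.14 (SD, n = 3 per group).

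Of the 20 clock genes measured, 14 passed when adjusted over the list alone, 3 of them higher and 11 lower. Among the lower genes were Tef at -1.93 ± 0.22 (log2 difference ± SE), Bhlhe40 at -1.84 ± 0.26, Per1 at -1.07 ± 0.18 and Hlf at -1.24 ± 0.27. Nr1d2 fell by 2.43 on the log2 scale, Nr1d1 by 1.75, Per3 by 1.63, Per2 by 1.27 and Cry2 by 0.63. Dimmer probes of Per1 (-0.01 ± 0.15) and Cry2 (-0.20 ± 0.19) did not show the fall. Apart from Npas2, Tef, Dbp and Ciart, these members were named after their values were seen or because they were among the largest differences. The median of the list was -1.15 with a bootstrap interval from -1.69 to -0.07. Setting Ciart at its bound could not move this median, since Ciart lies far below it either way. Among the members that did not pass were Rora at 0.46 ± 0.26, Clock at 0.47 ± 0.28, Csnk1e at -0.18 ± 0.20 and Csnk1d at 0.03 ± 0.18. For Bhlhe41 the brightest probe gave -0.44 ± 0.34 and a dimmer probe -1.83 ± 0.34, and Cry1 was not among the probes tested.

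**Figure D1:**
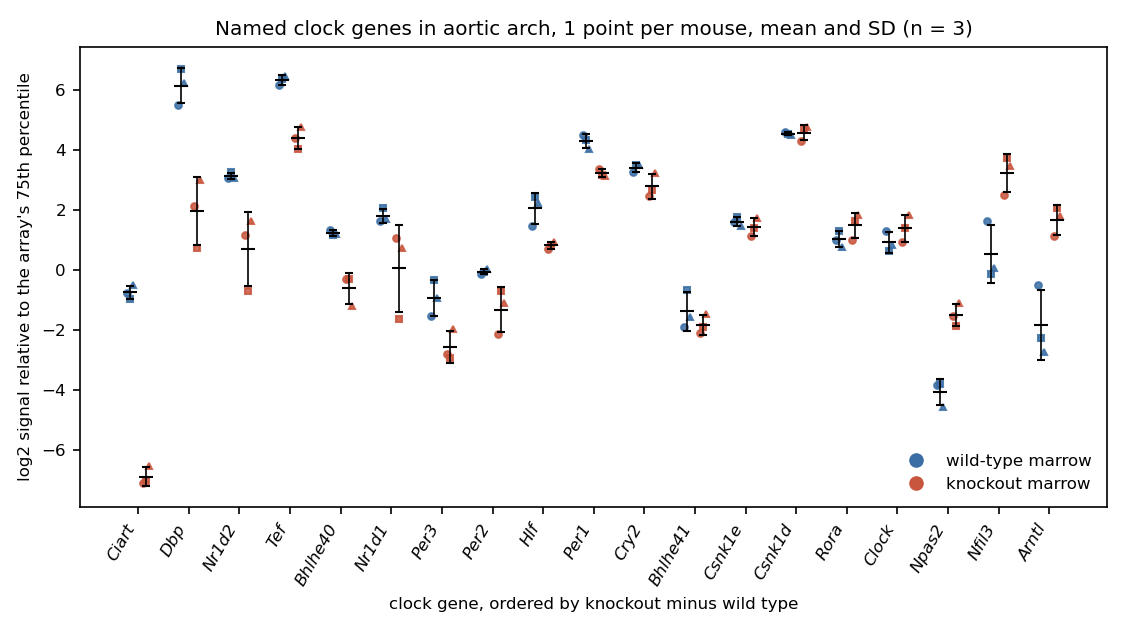
Log2 signal of the named clock genes relative to each array's 75th percentile, on the vertical axis, for wild-type (blue) and knockout (red) marrow, with 1 point per mouse (circle, square and triangle for replicates 1 to 3) and bars for mean and SD. Genes run from Ciart, whose knockout values at -6.91 on average are not well above background, to Arntl, which averages -1.85 and 1.66.

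Over all 38341 probes, Ciart alone passed the adjusted test (limma, adjusted p = 0.000242). Its knockout values were not well above background on any array, so their SD of 0.31 need not measure spread among mice. The p for Ciart rests partly on that SD. The clock list was lower by camera (adjusted p = 1.6e-05), with adjusted p = 0.84 with an estimated correlation. By fry, its adjusted p was 0.11 for movement in 1 direction and 0.00028 for change in either direction, and it was the only 1 of the 35 lists past the latter. The list median stayed between -1.04 and -0.87 when each array was left out in turn, and all these fits kept the camera call. The Ciart call ended when the variance was not moderated across probes (adjusted p = 0.13), and over the alternatives its adjusted p ran from 6.2e-05 to 0.13. The hour at which tissue was taken is not given in the sources used here.

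The Ciart probe lies on chromosome 3 at 95682433 to 95682492 of mm9, the Arntl probe on chromosome 7 at 120457261 to 120457320, the Dbp probe on chromosome 7 at 52965461 to 52965520 and the Npas2 probe on chromosome 1 at 39418941 to 39419000. A second Dbp probe gave -4.32 ± 0.60. The brightest probe assigned to Nr1d2 is placed by the files on chromosome 19, and a second Nr1d2 probe gave -2.25 ± 0.47.

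Xaf1, a pro-apoptotic antagonist of the caspase inhibitor Xiap, differed at 1 of its 2 probes. The downstream probe was 7.54-fold higher with knockout marrow, from -3.98 ± 0.23 to -1.07 ± 0.40 (SD, n = 3 per group), with all 3 knockout arrays above all 3 wild-type arrays. The upstream probe, which was the brighter, read 0.65 ± 0.04 and 0.63 ± 0.26, a difference of -0.02 ± 0.18. Pdcd4, a translation inhibitor and established miR-21 target, was 0.41 ± 0.26 higher, which did not pass (adjusted p = 0.68).

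The downstream Xaf1 probe had the second smallest p of all tested probes, with an adjusted p of 0.066 that missed the threshold (limma). It passed with normexp (0.037), with median centring (0.045), with a trended robust variance (0.027), with array weights (0.023) and without knockout replicate 3 (0.034). Across the alternatives its adjusted p ran up to 0.51, and its difference was 1.49 with normexp. The upstream probe changed sign without knockout replicate 2 (0.07) or 3 (0.03), without both (0.27) and with the adipocyte covariate (0.18). The upstream probe, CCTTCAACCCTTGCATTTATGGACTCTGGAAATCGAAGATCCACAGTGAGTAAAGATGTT, lies on chromosome 11 of mm9 at 72122169 to 72122228. The downstream probe, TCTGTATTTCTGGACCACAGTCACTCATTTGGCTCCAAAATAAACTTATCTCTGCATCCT, lies on the same chromosome at 72127175 to 72127234, and both carry the same transcript accession in the files.

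**Figure D2:**
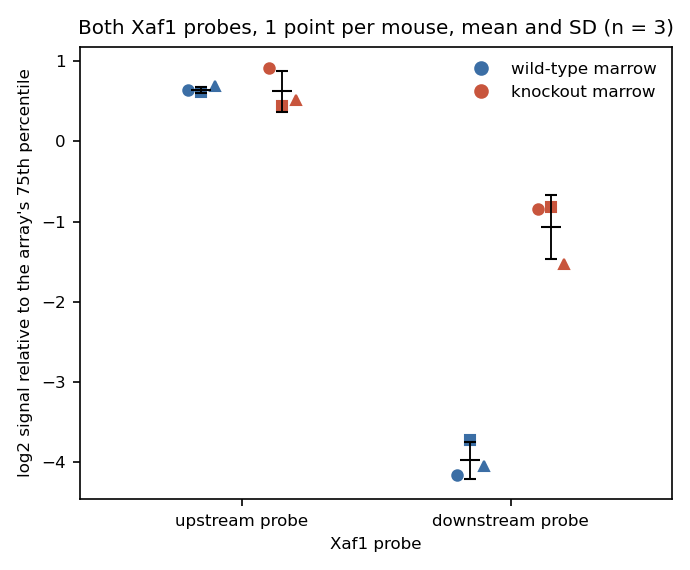
Log2 signal of both Xaf1 probes relative to each array's 75th percentile, on the vertical axis, for wild-type (blue) and knockout (red) marrow, with 1 point per mouse and bars for mean and SD. The upstream probe averages 0.65 and 0.63, and the downstream probe -3.98 and -1.07.

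Other apoptosis genes were not called by camera as groups, which with 3 arrays per group does not exclude a difference. The 29 measured pro-apoptotic genes had a median of 0.08 and the 17 anti-apoptotic genes a median of 0.06, with 0 members of either past the test when adjusted over the list alone. Tnfsf10, encoding the death ligand TRAIL, read -0.75 ± 0.26 and Fasl -0.61 ± 0.23. Among the survival genes Birc3 read 0.31 ± 0.18 and Cflar 0.26 ± 0.18. The 32 measured published miR-21 targets had a median of -0.03 with an interval from -0.16 to 0.13, with Fasl and Acat1 (-1.07 ± 0.43) having the smallest p. The target median was 0.03 without wild-type replicate 1, 0.04 without knockout replicate 1 and -0.19 without knockout replicates 2 and 3, where camera called it lower, and the anti-apoptotic median was -0.02 without knockout replicate 2. The 21 p53 targets had a median of 0.02, and Plk2 at -0.70 ± 0.15 was the only member that passed (adjusted p = 0.044, adjusted over the list alone). Xaf1 is represented in these lists by its upstream probe where it occurs.

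Fat-cell genes were lower in the knockout arches by camera (adjusted p = 0.84 with an estimated correlation), and this difference rested on replicates 2 and 3 of that group. Brown adipocyte markers had a median of -1.68 over 20 genes and white adipocyte markers -1.52 over 20 genes. Elovl3 read -3.37 ± 1.09, Elovl6 -2.54 ± 0.94, Fabp3 -1.68 ± 0.73 and Ucp1, the uncoupling protein of brown fat, -2.30 ± 1.03. Fasn, the fatty acid synthase, read -2.43 ± 0.94, Fabp4 -1.79 ± 0.74, Slc2a4 -1.44 ± 0.56 and Pnpla2 -1.37 ± 0.56. The mean of both marker lists, as a deviation from the average array, was 0.99, 0.16 and 1.17 on the wild-type arrays and 1.10, -1.24 and -2.18 on the knockout arrays.

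Respiratory chain, glycolysis and sterol synthesis genes were also lower by camera (adjusted p = 0.84 with an estimated correlation). The first 2 of these lists were lowest on knockout replicates 2 and 3, as the fat-cell genes were. Sterol synthesis genes averaged 0.02, -0.01 and 0.46 on the wild-type arrays and -0.13, -0.13 and -0.21 on the 3 knockout arrays. Wild-type replicate 3 thus stood apart. The 25 respiratory chain genes had a median of -0.69, with Cox5b at -0.96 ± 0.49, Ndufv1 at -0.76 ± 0.41, Ndufa4 at -0.76 ± 0.40 and Sdhb at -0.90 ± 0.51. The 23 hypoxia and glycolysis genes had a median of -0.33, with Hk2 at -1.59 ± 0.50, Pdk1 at -1.20 ± 0.43, Bnip3 at -0.96 ± 0.40 and Pfkfb3 at -0.75 ± 0.31. The 21 sterol synthesis genes had a median of -0.24, with Sc5d at -0.69 ± 0.26, Idi1 at -0.58 ± 0.23, Stard4 at -0.52 ± 0.24 and Nsdhl at -0.53 ± 0.26.

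Immature thymocyte markers had a median of -0.60 over 14 genes, with Arpp21 at -0.53 ± 0.17, Tcf7 at -1.11 ± 0.42, Rag2 at -0.67 ± 0.26 and Cd8a at 0.36 ± 0.17. Their array means were 0.33, 0.28 and 0.44 with wild-type marrow and 0.48, -1.01 and -0.52 with knockout marrow, low on the same arrays as the fat-cell genes. With normexp the thymocyte median was -0.08 and the call ended (adjusted p = 0.11). Endothelial markers had a median of -0.18 over 22 genes, with the receptor Flt1 at -0.65 ± 0.24, Esam at -0.38 ± 0.16, Lyve1 at -1.24 ± 0.56 and Cdh5 at -1.09 ± 0.50. They averaged 0.21, 0.16 and 0.12 on the wild-type arrays and 0.15, -0.05 and -0.59 on the knockout arrays. Both lists had adjusted p = 0.84 with an estimated correlation.

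Matrix and smooth muscle genes had medians slightly above 0 and were called higher by camera (adjusted p = 0.84 with an estimated correlation), but both calls ended with normexp (adjusted p = 0.088 and 0.12). Fibroblast and extracellular matrix genes had a median of 0.24 over 25 genes, with elastin (Eln) at 0.84 ± 0.26, its cross-linking enzyme Lox at 1.01 ± 0.38, Bgn at 0.51 ± 0.20 and Mfap5 at 0.43 ± 0.22. Contractile smooth muscle markers had a median of 0.20 over 22 genes, with Myh11 at 0.78 ± 0.24, Mylk at 0.49 ± 0.26, Myocd at 0.56 ± 0.30 and Acta2 at 0.28 ± 0.20. Smooth muscle averaged -0.16, 0.02 and -0.17 on the wild-type arrays and -0.28, 0.23 and 0.37 on the knockout arrays, so that knockout replicate 1 was the lowest of all 6 and the arrays poor in fat-cell genes the highest. Cardiac muscle markers had a median of 0.55 over 18 genes, with Tnnt2 at 0.72 ± 0.28, Nppa at 1.83 ± 0.87, Nppb at 0.48 ± 0.23 and Myl4 at 0.81 ± 0.46. They averaged -0.26, -0.27 and -0.32 on the wild-type arrays and 1.23, -0.98 and 0.60 on the knockout arrays, with knockout replicate 2 the lowest of all 6. Immediate early genes had a median of 0.29 over 22 genes, with Nr4a1 at 1.27 ± 0.43, Fosb at 0.42 ± 0.17 and Jund at 0.45 ± 0.19, while Ier3 read -0.76 ± 0.18. Immediate early genes averaged 0.04, -0.15 and -0.26 on the wild-type arrays and 0.01, 0.32 and 0.03 on the knockout arrays, highest on knockout replicate 2. Efferocytosis genes, used in the clearance of dying cells, had a median of 0.19 over 26 genes, with Itgb3 at 0.44 ± 0.20, Timd4 at 0.58 ± 0.32 and Stab2 at 0.74 ± 0.41, while Cd36, which adipocytes also express, read -1.95 ± 0.96. They averaged 0.06, -0.13 and -0.10 on the wild-type arrays and -0.03, 0.36 and -0.16 on the knockout arrays, so that knockout replicate 2 stood apart and knockout replicate 3 was the lowest of all 6.

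**Figure D3:**
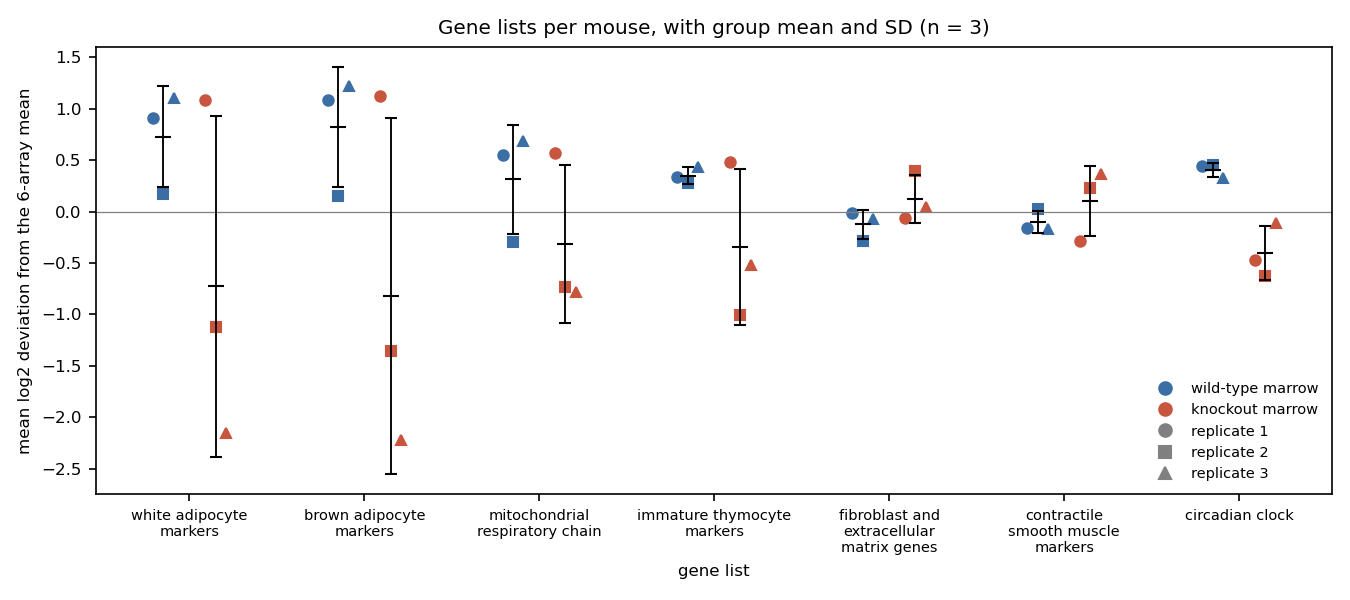
Mean log2 deviation of 7 gene lists from the mean of all 6 arrays, on the vertical axis, for wild-type (blue) and knockout (red) marrow, with 1 point per mouse (circle, square and triangle for replicates 1 to 3) and bars for group mean and SD. In both adipocyte lists knockout replicate 1 sits with the wild-type arrays and knockout replicates 2 and 3 lie below all others, while all 3 knockout arrays lie below all wild-type arrays in the clock list.

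By camera 13 of the 35 lists passed, 5 higher and 8 lower, 10 passed with normexp, 1 higher and 9 lower, and 7 with the adipocyte covariate, 6 higher and 1 lower. The covariate is the mean of the adipocyte lists themselves, so that fit tests nothing about them. Each of the 13 had adjusted p = 0.84 with an estimated correlation, and none of the members outside the clock list passed when adjusted over its list alone. Without knockout replicates 2 and 3 the medians were 0.27 for white and 0.31 for brown adipocyte markers, 0.24 for the respiratory chain, 0.02 for hypoxia and glycolysis, 0.24 for thymocyte markers, -0.22 for smooth muscle and -0.03 for efferocytosis, each the opposite sign. With knockout replicate 1 left out, the medians were -2.50 for white and -2.72 for brown adipocyte markers and -1.17 for the respiratory chain, and with knockout replicate 3 left out they were -0.87, -1.04 and -0.42. Normexp ended the thymocyte (-0.08), matrix (0.18), smooth muscle (0.15), immediate early (0.25) and efferocytosis (0.17) calls. Quantile normalization ended the smooth muscle call (0.16), no filter on dim probes the cardiac (0.48) and efferocytosis (0.19) calls, and array weights the cardiac call (0.23). Single arrays also ended calls. The thymocyte (-0.36), matrix (0.08), smooth muscle (0.17), immediate early (0.13) and efferocytosis (0.02) calls ended without knockout replicate 2. The smooth muscle (0.08), cardiac (0.40) and endothelial (-0.13) calls ended without knockout replicate 3. The cardiac (0.13) and sterol (-0.30) calls ended without knockout replicate 1. The matrix (0.18), cardiac (0.59), immediate early (0.28), efferocytosis (0.18) and endothelial (-0.26) calls ended without wild-type replicate 2, and the sterol (-0.08), immediate early (0.25) and efferocytosis (0.12) calls without wild-type replicate 3. Calls that held moved to -0.96 for thymocyte markers and 0.40 for smooth muscle without knockout replicate 1, to -0.28 for endothelial markers without knockout replicate 2 and to -0.20 for hypoxia and glycolysis without knockout replicate 3. They moved to 0.10 for smooth muscle without wild-type replicate 1, and to 0.30 for smooth muscle and -0.37 for sterol synthesis without wild-type replicate 2.

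Immune cell and inflammation lists did not pass as reported, and some did under single alternatives. Macrophage and monocyte markers had a median of 0.15 over 22 genes, with lysozyme (Lyz2) at 1.64 ± 0.55 and Cd300a at -0.91 ± 0.33. Foam cell genes had a median of 0.07, antigen presentation by MHC class II 0.22, inflammatory cytokines and chemokines 0.02, T and NK cell markers 0.05, B and plasma cell markers 0.09, and neutrophil, mast cell and platelet markers -0.02. Interferon-stimulated genes had a median of -0.14 over 33 genes (adjusted p = 0.062), with Usp18 at -0.56 ± 0.17. Leaving out 1 array at a time, macrophage medians ran from -0.25 (without knockout replicate 2) to 0.49 (without knockout replicate 3), foam cell genes from -0.28 to 0.45 and cytokines from -0.17 to 0.42 without the same arrays. MHC class II ran from 0.01 (without knockout replicate 1) to 0.45 (without knockout replicate 3), with 0.09 without wild-type replicate 2 and 0.11 without knockout replicate 2. Camera called these lists higher without knockout replicate 3, foam cell genes lower without knockout replicate 2 and MHC class II higher without wild-type replicate 3 (0.27). Macrophage markers (-0.05) and cytokines (-0.05) also changed sign without wild-type replicate 2, and cytokines (-0.13) without knockout replicate 1. Interferon-stimulated genes were called lower with normexp (-0.10, adjusted p = 0.021), no filter on dim probes (-0.14, adjusted p = 0.031), the replicate block (adjusted p = 0.047) and array weights (-0.23, adjusted p = 0.0087), as well as without wild-type replicate 1 (-0.19) or knockout replicate 1 (-0.31). Their median was -0.06 without wild-type replicate 3 and -0.05 without knockout replicate 3. T and NK cell (0.16) and B and plasma cell markers (0.29) were called without knockout replicate 2, and had medians of -0.05 and -0.08 without knockout replicate 1. B and plasma cell markers also changed sign without wild-type replicate 2 (-0.03) or knockout replicate 3 (-0.04), and neutrophil, mast cell and platelet markers without wild-type replicate 2 (0.46) or knockout replicate 3 (0.17).

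The remaining lists gave medians of -0.17 for the unfolded protein response, 0.14 for the cell cycle, 0.12 for lysosome and autophagy, 0.01 for osteochondrogenic genes and 0.03 for the chromosome 11 neighbours of Mir21a. Medians were -0.11 for neuronal and Schwann cells, -0.22 for parathyroid, thyroid and airway epithelium, -0.27 for skeletal muscle, 0.22 for erythroid and 0.24 for mesothelial markers. Aggrecan (Acan), in the osteochondrogenic list, at -1.09 ± 0.19 and Tcap, in the skeletal muscle list, at -1.98 ± 0.41 passed when adjusted over their lists alone. For osteochondrogenic genes and the Mir21a neighbours the camera direction was down, and for neutrophil, mast cell and platelet markers up, against the sign of the median. Skeletal muscle was called higher without wild-type replicate 1 (0.62) and lower without wild-type replicate 2 (-0.88). The unfolded protein response was called lower with normexp (-0.19, adjusted p = 0.0014), no filter on dim probes (adjusted p = 0.042) and probes above background on all 6 arrays (adjusted p = 0.039), as well as without wild-type replicate 2 (-0.28) or knockout replicate 2 (-0.25), with medians of -0.01 without wild-type replicate 1 and -0.03 without knockout replicate 1. Mesothelial markers were called higher without knockout replicate 2 (1.16), and their median was -0.33 without wild-type replicate 2 and -0.40 without knockout replicate 1. Erythroid markers were called higher without knockout replicate 2 (0.48), and their median was -0.10 without wild-type replicate 1. The cell cycle was called without knockout replicate 3 (0.21), with 0.07 without knockout replicate 2. Lysosome and autophagy genes were called without wild-type replicate 1 (0.15), knockout replicate 1 (0.21) or knockout replicate 3 (0.18), changed sign without knockout replicate 2 (-0.07), and were called with array weights (0.21) and with the mean over a gene's probes (0.12), and mesothelial markers with the replicate block (adjusted p = 0.019).

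**Figure D4:**
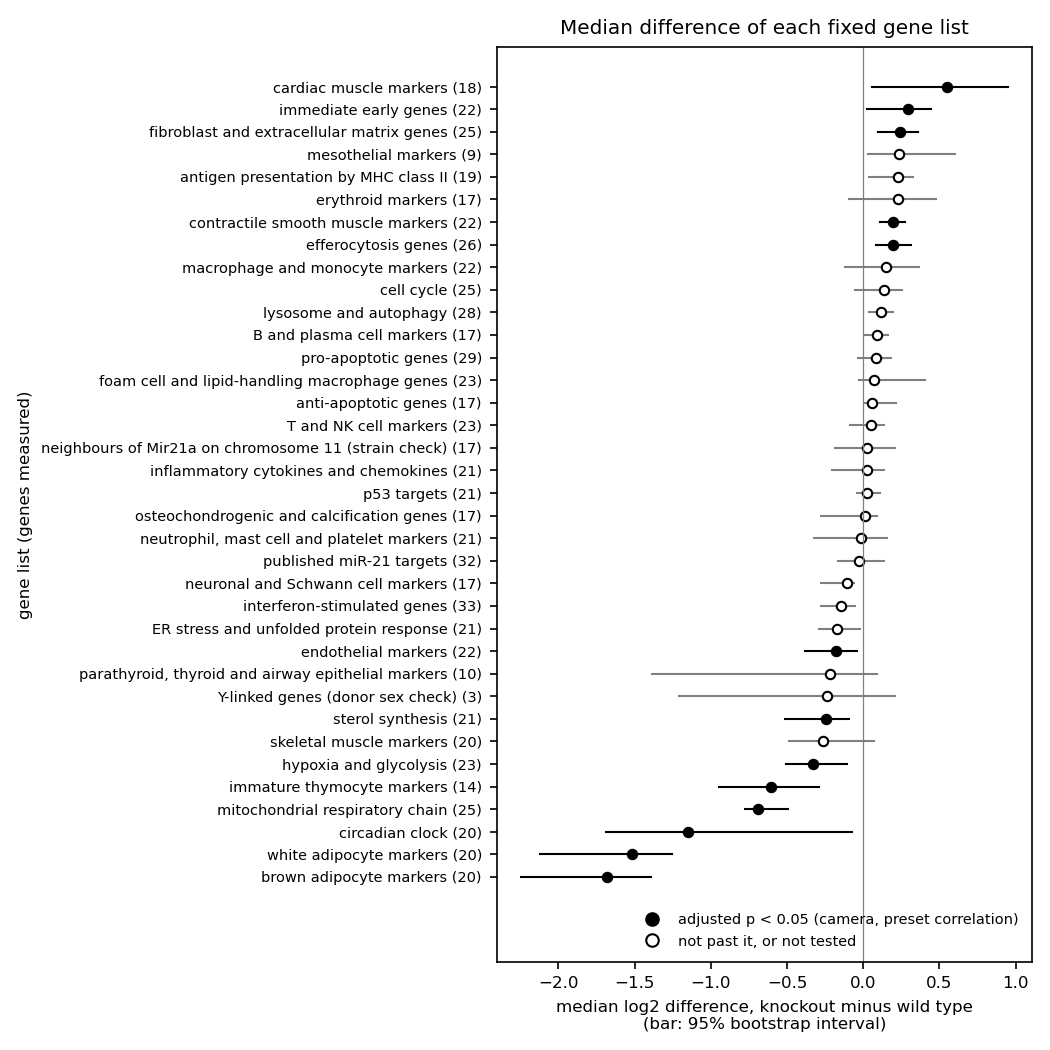
Median log2 difference of each of the 36 gene lists, knockout minus wild-type marrow, on the horizontal axis, with 95% bootstrap intervals over genes and the number of measured genes in brackets. Filled points mark the 13 lists past adjusted p of 0.05 by camera with its preset correlation, from -1.68 for brown adipocyte to 0.55 for cardiac muscle markers.

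Beyond the clock, the largest differences by the naming rule did not pass the adjusted test. Higher were the seminal vesicle gene Svs5 at 4.41 ± 1.12, the forkhead factor Foxs1 at 1.70 ± 0.25, Rasl11a at 1.66 ± 0.35, the aggrecan-cleaving protease Adamts4 at 1.55 ± 0.29, Ostn at 1.45 ± 0.32 and Tmem82 at 1.42 ± 0.30. A second Adamts4 probe gave 1.44 ± 0.27. Lower were the secretoglobin Scgb3a1 at -4.01 ± 1.14, the neurotensin receptor Ntsr2 at -2.76 ± 0.78 with a second probe at -1.16 ± 0.37, Mogat1 at -2.43 ± 0.65, the organic cation transporter Slc22a3 at -2.31 ± 0.62 and Ccdc122 at -2.14 ± 0.49. The olfactory receptor Olfr734 was at least 3.46-fold lower. Scgb3a1, Ntsr2, Mogat1, Slc22a3 and Ccdc122 were well above background on 1 of the 3 knockout arrays, and Svs5 and Ostn on 2 of the 3 wild-type arrays. For Ntsr2, Mogat1 and Slc22a3 knockout replicate 1 (-3.58, -2.96 and -4.46) lay near the lowest wild-type array (-3.63, -2.85 and -4.22). Knockout replicates 2 and 3, the arrays low in fat-cell markers, lay below it. The groups overlapped for Ntsr2.

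In all, 0 probes were higher and 1 was lower at adjusted p below 0.05 (limma), and 3339 probes, 1703 higher and 1636 lower, lay below 0.05 unadjusted, where chance gives 1917. With normexp that split was 1857 higher and 1107 lower. Leaving out wild-type replicate 3 gave 1566 such probes and leaving out knockout replicate 1 gave 6858. The groups did not overlap for 13.7% of probes, where chance gives 10%. An exact permutation of 3 against 3 arrays cannot give p below 0.1.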

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

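The adipocyte covariate, the fit without knockout replicates 2 and 3 and the test of lists in either direction were chosen after seeing the data. Probes past the adjusted test numbered 1 as reported, with quantile normalization, no filter, the authors' series table and the replicate block. There were 4 with normexp, 2 each with median centring, trended robust variance, array weights, an adjusted p below 0.1 and the adipocyte covariate, 6 without knockout replicates 2 and 3, and 2017 by unadjusted p below 0.05 and a fold of at least 1.5. There were 0 with unmoderated variances and 0 with probes above background on all 6 arrays, a filter that leaves Ciart out. Leaving out each array in turn gave 1 to 3. Probes below 0.05 unadjusted ranged from 1566 to 6858 over those fits and reached 7163 with array weights. Lists past camera numbered 10 to 16 over them, with 5 higher and 8 lower as reported, 1 and 9 without wild-type replicate 2 and 9 and 7 without knockout replicate 3. They numbered 7 with the adipocyte covariate, 6 higher and 1 lower, 0 with an estimated correlation, 0 by fry and 1 by fry in either direction. The clock list kept its camera call in every fit that used the preset correlation. With the adipocyte covariate the medians of smooth muscle (-0.13) and the respiratory chain (0.11) changed sign. Without knockout replicates 2 and 3 so did efferocytosis (-0.028), thymocyte (0.24), neutrophil, mast cell and platelet (0.36), smooth muscle (-0.22), white (0.27) and brown adipocyte (0.31), hypoxia and glycolysis (0.0196), respiratory chain (0.24) and Mir21a neighbours (-0.31). With 1 knockout array left, that array is assumed to vary like the wild-type ones. Over the fits leaving out 1 array, skeletal muscle ran from -0.88 to 0.62, with the sign changed without wild-type replicate 1, and foam cell genes from -0.28 to 0.45, with the sign changed without knockout replicate 2. Beyond the fewer arrays in these fits, the cause was not tested. Same-numbered arrays correlated at 0.12, 0.05 and -0.28 in their deviations, so the numbers were not taken as pairs. With them as a replicate block, 1 probe passed, 3041 lay below 0.05 unadjusted and 15 lists passed. The series table repeats the scanner values and tests little. The slide or scan block was not possible with 1 slide and 1 scan, and seed-site tests were not run. Probes near background, such as Ciart in the knockout group, have no measured fold: its difference was -6.15 as reported and -1.95 with normexp.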

Other observations

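The share of signal lost by Dbp, the range of fat-cell markers within a group, the adipocyte covariate, the glucocorticoid-induced genes without each array and the slide bound over all clock genes were tests chosen only after the results were seen, as was the list of clock genes that peak opposite to Bmal1. Of the 11 genes of that list, 10 lay lower at an unadjusted p below 0.05 and Bhlhe41 read -0.44 ± 0.34 (median -1.75, camera p = 5e-20, p = 0.0028 with an estimated correlation). The list was drawn from genes whose values had been seen.

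Y-linked transcripts were measured in arches from female recipients in both groups. Ddx3y read 1.71 ± 0.09 with knockout marrow, a difference of 0.21 ± 0.15 (SE), and Eif2s3y read 2.38 ± 0.12 and 2.14 ± 0.22 (SD, n = 3 per group, wild-type first), well above background on all 6 arrays, and Uty read -2.51 ± 1.33 and -3.72 ± 0.35. Their median difference was -0.24 over 3 genes, too few for a test. Among 6433 probe pairs of 5121 genes, the gap between the Xaf1 probes changed with the smallest p (difference of 2.94 ± 0.24, adjusted p = 0.079), and 0 pairs passed.

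The clock genes differed in a coordinated way between the groups. Slide row and group cannot be told apart by design, so a row effect on the clock genes alone is not excluded. A row shift common to all probes was not tested, since each array was centred on its spike-in median, which removes it. Before centring these log2 medians were 9.94, 10.52 and 10.04 on the wild-type arrays and 9.96, 10.47 and 11.17 on the knockout arrays. A row effect of the clock genes' size that varies from probe to probe is argued against by 10 spike-in probes. They differed between the slide rows by 0.17 on average and 0.47 at most, with an interval over probes, not arrays, up to 0.25. The bound set in advance was 0.377, from the median size of 1.89 of the 14 clock genes at an unadjusted p below 0.05. The same bound from all 20 measured (1.45) was 0.29, and the interval lay under both, though the largest difference did not. A different hour of tissue collection stays open, because no hour is given and the criterion set in advance for it was met by glucocorticoid-induced genes (median -0.44, camera value 0.0057, or 0.45 with an estimated correlation), though not by 14 heat shock genes (0.70). That value rested on wild-type replicate 1, without which the median was -0.004 (0.70), and was also lost without knockout replicate 3 (-0.18, 0.22) and with the adipocyte covariate (-0.03, 0.77), so it decides nothing. A change confined to marrow-derived cells would need these to supply at least the 94.5% of Dbp signal that was lost, a share not measured here, and an effect of miR-21 on the clock of the arch also stays open.

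The downstream Xaf1 probe was higher with knockout marrow while the upstream probe was not. A general interferon response is argued against, since the other 32 interferon-stimulated genes had a median of -0.14 with an interval from -0.27 to -0.05. Release of miR-21 targets as a set stays open, with a median of -0.0285 for the other 31 targets, whose interval from -0.16 to 0.16 leaves room for a small rise. A donor chromosome segment around Mir21a, on the same chromosome, also stays open: 4.95% of the 222 genes between the 2 loci lay below 0.05 unadjusted, within the 4.05% to 10.8% of equal runs elsewhere. A transcript with a different 3′ end is a candidate explanation that these probes cannot separate from a sequence difference under the probe.

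Fat-cell markers were lower on average with knockout marrow. The knockout arrays spanned 3.28 on the log2 scale, more than the difference of -1.55 between the group means, which is consistent with different amounts of fat in the dissected pieces. Whether that fat came with dissection or differed between the mice was not tested.

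The 6 arrays allow 10 splits into 3 and 3, too few for a share below 0.05. In 2 of them, the real one included, at least as many probes passed the adjusted test (1 in the real split, 429 at most in another), and 2 gave at least as many probes at unadjusted p below 0.05 (3339 real, 7192 at most). For lists past camera it was 8 splits (13 real, 23 at most in another). The split with 429 set knockout replicate 1 and wild-type replicates 1 and 3 against the rest, the same division as high and low fat-cell markers, which points to a structure of the samples. By fry in either direction the clock list gave 7.9e-06 in the real split and at least 0.20 in the others.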
